A study of Homo sapiens with 11 samples.

How the data were processed

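RNA was measured in cells grown from RUES2, an established human embryonic stem cell line, that had been directed through endoderm and foregut stages to lung progenitors. Bulk poly-A RNA-seq covered 3 groups of 3 libraries: progenitors at day 25, and cells matured to day 50 with or without CHIR, an inhibitor of the kinase GSK3. Single-cell RNA-seq covered day 50 cells, with 1 library per condition. Maturation medium held dexamethasone, cyclic AMP and the phosphodiesterase inhibitor IBMX in both conditions, per the labels.

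The authors deposited bulk read counts per gene, not normalized, in a table keyed by Ensembl identifiers with all 9 libraries and in a second table keyed by gene symbols with the 6 day 50 libraries. The submitters' processing notes name bcl2fastq 2.17, STAR 2.5.2b, featureCounts 1.5.0-p3 and DESeq. The genome annotation and the strand setting behind the bulk counts are not given in the sources used here, so no coordinates are reported. The authors also deposited UMI counts per gene and barcode from Cell Ranger 2.0.0 on GRCh38, per the submitters' processing notes.

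The Ensembl table held 22875 genes. A name table gave symbols to 22513 of them, and the 362 without one took at most 0.69% of the counts of a library. The symbol table held 25559 genes, of which 26 carried names turned into dates, and it served only as an alternative. Of 19142 symbols in both tables, 19116 had identical counts. Of 14695 symbol table genes with at least 100 counts, 552 had no row of identical counts in the Ensembl table. The Ensembl table held 0 mitochondrially encoded genes. Libraries ranged from 17258146 to 26583181 counts.

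Bulk counts were tested with edgeR 4.0.16 (R 4.3.3): TMM scaling, the default filterByExpr filter, a quasi-likelihood fit of all 9 libraries with group as the only term, and Benjamini-Hochberg adjustment with a threshold of 0.05. All adjusted p-values of single genes come from this test unless another is named. CPM are counts scaled to a common TMM library size. Standard errors were taken from the fold change and the F statistic. Fold changes used the default prior count of edgeR. Log-CPM values, used for principal components and gene lists, had a prior count of 2. Where a group had 0 counts in all its libraries, a fold is a lower bound against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio is given with its 95% counting interval. Intervals and floors cover counting error only. The labels do not say whether the replicates of a group were separate cultures. If they were not, p-values measure only the spread between these samples. All 9 pairs of replicates differed by more than counting noise, with chi-square per degree of freedom from 15.05 to 145.

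A total of 21 gene lists were fixed in advance, with 297 members, 295 of them in the Ensembl table. Each list was tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 21 lists, and again with the correlation estimated from the data. The genes named were also chosen by a rule fixed in advance. For each bulk comparison the rule took the 4 genes with the largest change each way among called genes with an established symbol, at least 5 CPM in every library of the higher group and no overlap between groups. It added the 2 members of each list with the smallest p for the day 50 groups, or 1 member for the comparisons with day 25, and 12 genes named whatever their values. For the single-cell libraries it took the 6 highest and 6 lowest ratios among genes with at least 200 UMIs in the higher library, and the same 12 genes. A name from outside the rule is said to be so where it appears.

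Single-cell barcodes were kept with at least 500 genes and at most 20% mitochondrial UMIs. Scrublet at an expected doublet share of 2.5% marked 1 barcode in each library, 0.04% and 0.03%, so doublet detection is regarded as having failed and doublets remain among the cells. Counts were normalised to 10000 per cell, log-transformed and reduced to 2000 variable genes and 30 principal components in scanpy 1.11.5. Leiden clustering used 15 neighbours and a resolution of 0.8, without integration of the libraries. Clusterings with genes scaled to unit variance were run first. The reported clusters use unscaled values, as set before the data were examined. The rule for naming a cluster was tightened after clusters had been seen: at least 3 of the markers fixed in advance had to be raised at least 2-fold with at least 10 UMIs, more than for any other class, and at least 1 had to be among the 10 leading genes. No other class could have more of its markers among those 10 leading genes. With 1 library per condition no test between conditions was made. UMIs of kept cells were summed per library, and ratios of CPM have exact Poisson intervals. The median log2 ratio of each list was set against 10000 random lists of the same size matched on mean expression, for members with at least 20 UMIs.

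The bulk test was tried on simulated counts for 14887 genes in the comparison without against with CHIR. Of these genes, 100 were changed 2-fold and 100 were changed 4-fold. The test recovered 27% of 2-fold and 87% of 4-fold changes, and 6 of 120 calls were unchanged genes. In the data 47.9% of genes were called in that comparison, so these shares need not hold there. The single-cell list step was tried on 33694 genes with a planted 4-fold list: its median was 1.98 at percentile 100, and 2 of 18 other lists fell under percentile 2.5 or over 97.5. Alternatives covered DESeq2 1.42.0 (size factors and Wald test), the low-count filters, the 2 groups alone, a replicate block, each library left out, a threshold of 0.01, the symbol table, and the single-cell filters and clustering. All columns of per-sample values in the bulk tables were matched to samples.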

Results

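The 9 bulk libraries held 17258146 to 26583181 counts, and 15098 genes were tested. The 3 groups separated on the first 2 principal components, which carried 48.9% and 38.1% of the variance. The question set by the series is how lung progenitors mature when GSK3 is left active or is inhibited by CHIR, a compound that stabilises beta-catenin and so activates WNT signalling.

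Day 50 cells without CHIR had more transcript of SCGB3A2, TP63 and ALB than cells with CHIR, and less of NKX2-1. SCGB3A2 (ENSG00000164265), a secretoglobin of club cells, stood at 8077 ± 2745 CPM without CHIR and 4.08 ± 1.83 CPM with it (SD, n = 3 each), a log2 fold change of 10.95 (SE 0.57, edgeR adjusted p = 9.96e-07). TP63 (ENSG00000073282), the transcription factor of basal cells, stood at 59.7 ± 19.3 against 0.14 ± 0.12 CPM. NKX2-1 (ENSG00000136352), the transcription factor that marks lung fate, fell by 1.55 on the log2 scale, from 347 ± 5.17 CPM with CHIR to 119 ± 20.7 CPM without (SE 0.19, edgeR adjusted p = 0.000118). In all, edgeR called 7237 genes, 3825 higher and 3412 lower without CHIR, and 4601 of them changed at least 2-fold. The libraries of the groups did not overlap for 52.4% of genes tested, where chance gives 10%.

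**Figure D1:**
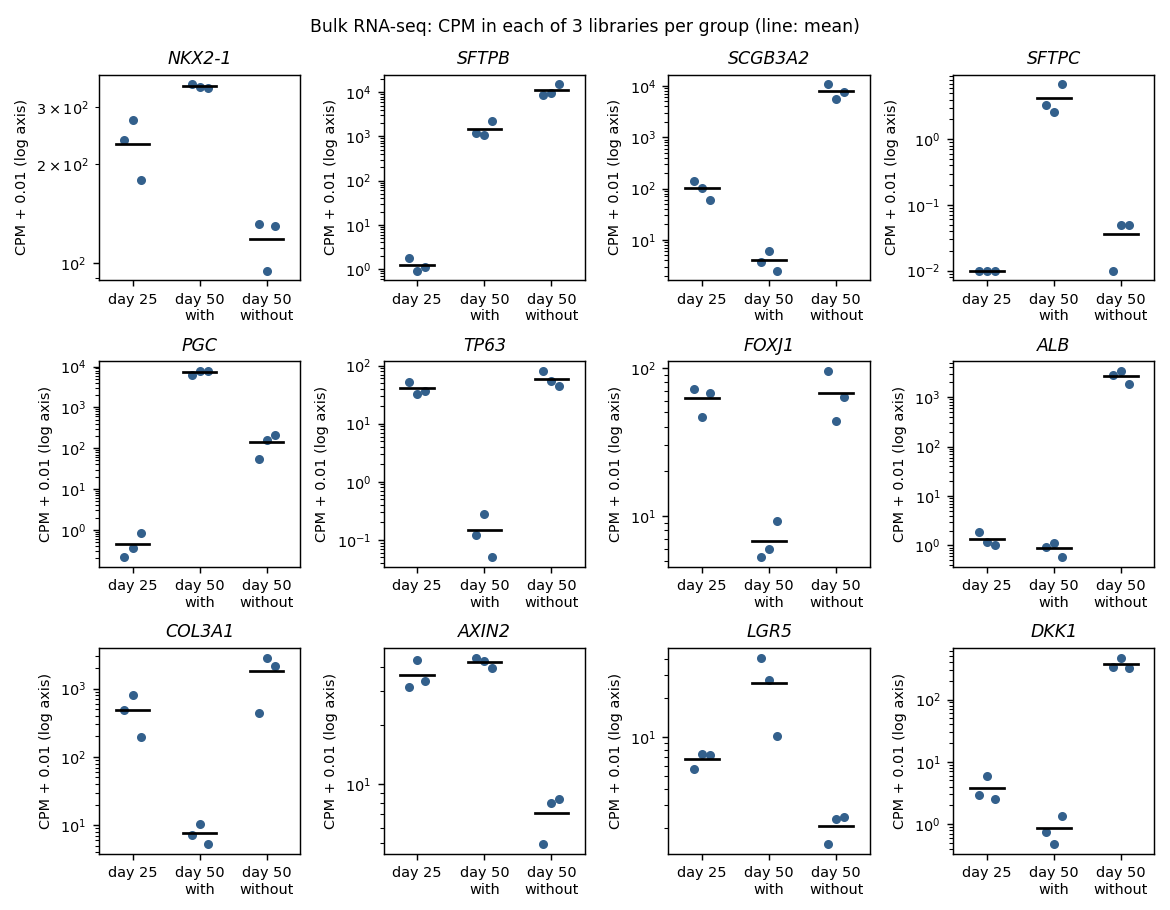
CPM plus 0.01 on a log axis for 12 genes in each bulk library, by group; points are libraries and lines are means of 3. SCGB3A2 and ALB were highest in the 3 libraries without CHIR, at means of 8077 and 2721 CPM, and PGC was highest with CHIR, at 7202 CPM.

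Of 15 measured WNT/beta-catenin target genes, 10 fell and 2 rose without CHIR (camera adjusted p = 0.00277; adjusted p = 0.36 with an estimated correlation; 10 and 2 also when adjusted over the list alone). AXIN2, a feedback inhibitor of the pathway, fell by 2.57 on the log2 scale to 7.11 ± 1.91 CPM, and RNF43, which removes WNT receptors from the cell surface, fell by 2.44. LGR5, a receptor for R-spondins, fell by 3.64. NOTUM, a secreted WNT deacylase, was among the genes with the largest decrease, from 150 ± 44.5 to 0.26 ± 0.28 CPM. The members that rose were DKK1, a secreted WNT antagonist, at 377 ± 82.7 against 0.84 ± 0.45 CPM, and the cyclin CCND1, which lies outside the naming rule. All 6 changes given here had an edgeR adjusted p of at most 0.00024.

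All 22 measured ciliated cell genes were called higher without CHIR (camera adjusted p = 6.52e-10; adjusted p = 0.25 with an estimated correlation), among them FOXJ1, the regulator of motile cilia, at 67.5 ± 26.2 against 6.8 ± 2.11 CPM, and CAPS at 98.1 ± 13.6 against 3.19 ± 1.48 CPM. Of 15 basal cell genes, 11 rose and 0 fell (camera adjusted p = 0.000164; adjusted p = 0.0853 with an estimated correlation), with COL17A1 at 154 ± 31.1 against 1.71 ± 0.87 CPM. Of 20 club and goblet secretory genes, 12 rose and 5 fell, or 13 and 5 adjusted over the list alone (camera adjusted p = 0.00579; adjusted p = 0.285 with an estimated correlation), and AGR3 rose by 5.44 on the log2 scale. Neuroendocrine genes showed 6 of 15 higher and 0 lower (adjusted p = 0.0189; adjusted p = 0.372 with an estimated correlation), with SCGN, a calcium-binding protein, at 18.8 ± 7.87 against 0.29 ± 0.2 CPM.

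Of 15 alveolar type 1 genes, 10 rose and 2 fell without CHIR (camera adjusted p = 0.00277; adjusted p = 0.165 with an estimated correlation), led by HOPX at 245 ± 19.9 against 28.7 ± 6.18 CPM and CAV1, of caveolae, at 168 ± 27.9 against 9.41 ± 2.59 CPM. AGER stood at 5.9 ± 1.49 against 10.7 ± 5.01 CPM and was not called (edgeR adjusted p = 0.0901), but it was called lower when with-CHIR replicate 1 was left out (adjusted p = 0.011). Of 17 alveolar type 2 genes, 4 rose and 8 fell, and the list was not called (camera adjusted p = 0.216). SFTPB, a surfactant protein, rose from 1489 ± 615 to 11356 ± 3624 CPM and SFTA2 rose by 3.08, while PGC fell from 7202 ± 951 to 144 ± 81.7 CPM. SFTPC, the surfactant protein specific to type 2 cells, had 289 counts over the 3 libraries with CHIR and 2 without, a ratio of 156 (95% counting interval 42.7 to 1290; edgeR adjusted p = 0.000143), and its mean with CHIR was only 4.29 ± 2.32 CPM.

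Of 20 lung field and distal tip progenitor genes, 11 fell and 2 rose without CHIR, or 12 and 2 when adjusted over the list alone (camera adjusted p = 0.0241; adjusted p = 0.372 with an estimated correlation). FOXP2 fell by 1.95 on the log2 scale. SOX2 and SOX9 were not called, with edgeR adjusted p of 0.657 and 0.903. Hypoxia and glycolysis genes showed 7 of 13 lower and 0 higher, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.0397; adjusted p = 0.498 with an estimated correlation), with CA9, a carbonic anhydrase, at 25.5 ± 15.4 against 212 ± 93.9 CPM; the list was not called without with-CHIR replicate 3 (adjusted p = 0.0834) or without-CHIR replicate 1 (adjusted p = 0.0909). Cell cycle genes had 4 of 24 higher and 11 lower, or 5 and 11 adjusted over the list alone, and were not called (adjusted p = 0.238). MKI67 fell by 0.92 (edgeR adjusted p = 0.0295), a call lost under 6 settings. Left out singly, with-CHIR replicates 1 and 2 and without-CHIR replicates 2 and 3 each ended it (adjusted p = 0.0764, 0.111, 0.113 and 0.0932), as did a fit of the 2 groups alone (0.0547) and the symbol table (0.0557).

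All 13 hepatic genes were called higher without CHIR (camera adjusted p = 2.73e-09; adjusted p = 0.222 with an estimated correlation): ALB, serum albumin, stood at 2721 ± 784 against 0.87 ± 0.27 CPM and APOH rose by 5.33. The 4 genes with the largest increase were GC, the vitamin D-binding protein, at 573 ± 88 against 0.08 ± 0.05 CPM, and CRP, KRT4 and SLC2A2, at least 1180-fold, 783-fold and 671-fold higher against 0 counts. KCNA3 was at least 203-fold lower, and ratios of SOX14 and POU3F2 with CHIR over without were 384 (106 to 3180) and 233 (79.3 to 1130). Of 14 mesenchymal genes, 12 rose and 2 fell (adjusted p = 0.00606; adjusted p = 0.4 with an estimated correlation), and their replicates were uneven: COL3A1 stood at 436, 2844 and 2138 CPM in the 3 libraries without CHIR against a mean of 7.64 ± 2.62 with it. DCN, LUM and VIM, named after their values were seen, stood at 116 ± 85.8, 96.3 ± 83 and 607 ± 138 CPM without CHIR and at 1.72 ± 1.65, 0.51 ± 0.59 and 1990 ± 177 CPM with it.

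Glucocorticoid-responsive genes rose without CHIR in 7 of 11 cases and fell in 0 (camera adjusted p = 0.00579; adjusted p = 0.224 with an estimated correlation), with FKBP5 at 492 ± 65.6 against 78.3 ± 9.16 CPM, although both media held dexamethasone. The cAMP-responsive list (5 of 10 higher and 2 lower, or 6 and 2 adjusted over the list alone) was not called (adjusted p = 0.163), and FOSB rose by 2.87. Notch pathway genes (7 of 13 higher, 1 lower) were not called (adjusted p = 0.0542), though the Notch ligand JAG1 rose from 17.9 ± 0.73 to 155 ± 13.9 CPM; the list was called when with-CHIR replicate 3, without-CHIR replicate 1 or without-CHIR replicate 2 was left out (adjusted p = 0.0294, 0.0492 and 0.0355). Intestinal genes had 4 of 8 higher and 0 lower, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.0377; adjusted p = 0.372 with an estimated correlation), with VIL1 of brush borders up by 3.29; leaving out with-CHIR replicate 3 or without-CHIR replicate 3 ended that call (adjusted p = 0.0588 and 0.0936). Squamous genes had 4 of 6 higher and 1 lower (adjusted p = 0.0628), and were called without with-CHIR replicate 2 (adjusted p = 0.0259). Endothelial and blood cell genes (1 of 5 higher, 3 lower), gastric genes (1 of 3 higher) and neuronal genes (3 of 8 lower) each had an adjusted p of 0.216, and pluripotency genes (2 of 5 higher, or 1 adjusted over the list alone) one of 0.478. Where no count adjusted over the list alone is given, in any of the 3 comparisons, it was equal to the count over all genes tested. DPPA4, 1 of the 2 pluripotency genes called, had 24 and 2 counts, a ratio of 11.1 (2.77 to 97.3; edgeR adjusted p = 0.0461), and was not called without any single library except without-CHIR replicate 1 (adjusted p = 0.0839 to 0.123).

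The members behind small counts, named after their values were seen, were as follows. Against the direction of their list, MYCN and SHH of the lung field rose, AQP5 and CLDN18 of alveolar type 1 cells fell, FOXA3, LTF, AGR2, CREB3L1 and WFDC2 of secretory cells fell, and TCF21 and VIM of the mesenchyme fell. SFTPA2, SFTPB, LAMP3 and SFTA2 were the alveolar type 2 genes that rose. The Notch target HES1 fell, as did KRT10 of squamous cells, CREM and PDE4D of the cAMP list, CD68, LAPTM5 and CD74 of blood cells, and TUBB3, STMN2 and MAP2 of neurons. KRT4, KRT13, KRT6A and KRT6B of squamous cells, SI, FABP1, VIL1 and ISX of the intestine, CTSE of the stomach, KDR of the endothelium and POU5F1 rose.

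From day 25 to day 50 with CHIR, PGC went from 0.45 ± 0.32 to 7202 ± 951 CPM, a log2 fold change of 13.95 (SE 0.74, n = 3 each, edgeR adjusted p = 1.07e-06), and SFTPB from 1.25 ± 0.43 to 1489 ± 615 CPM. SFTPC had 0 counts at day 25 and was at least 89.6-fold higher with CHIR. TP63 fell from 40.5 ± 10.4 to 0.14 ± 0.12 CPM, and SCGB3A2 from 100.3 ± 38.8 to 4.08 ± 1.83 CPM. The largest changes included FGL1, higher with CHIR, and EDN3, at least 942-fold lower. A total of 7485 genes were called, 3637 higher and 3848 lower, and 60.9% did not overlap between groups (10% by chance).

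With CHIR, 9 of 21 lists were called by camera against day 25, and 0 of them with an estimated correlation. Alveolar type 2 genes rose in 12 of 17 cases and fell in 0, or 12 and 1 adjusted over the list alone (camera adjusted p = 2.81e-05; adjusted p = 0.25 with an estimated correlation). Glucocorticoid-responsive genes rose in 10 of 11 and cAMP-responsive genes in 8 of 10 with 1 lower (adjusted p = 2.81e-05 and 0.00134; adjusted p = 0.0989 for both with an estimated correlation), as in ERRFI1, up by 2.71, and PPARGC1A, up by 3.37. Hypoxia and glycolysis genes rose in 9 of 13 (adjusted p = 0.000638; adjusted p = 0.421 with an estimated correlation), with NDRG1 up by 4.42. Cell cycle genes fell in 19 of 24, or 20 adjusted over the list alone (camera adjusted p = 1.99e-06; adjusted p = 0.25 with an estimated correlation), led by MCM5, a replication helicase subunit, which fell by 3.19. Mesenchymal genes fell in 12 of 14 with 1 higher (adjusted p = 0.0104; adjusted p = 0.513 with an estimated correlation), ciliated genes in 9 of 22 with 1 higher (adjusted p = 0.0344; adjusted p = 0.521 with an estimated correlation), and pluripotency genes in 4 of 5 (adjusted p = 0.00436; adjusted p = 0.151 with an estimated correlation). Club and goblet genes rose in 10 of 20 and fell in 3 (adjusted p = 0.0438; adjusted p = 0.385 with an estimated correlation), a call lost without day 25 replicate 2 (adjusted p = 0.0568) or with-CHIR replicate 3 (adjusted p = 0.0517). NKX2-1 rose by 0.59 (edgeR adjusted p = 0.0226), which was lost without day 25 replicate 3 (adjusted p = 0.0703) or with-CHIR replicate 2 (adjusted p = 0.0535), while AXIN2 was not called (adjusted p = 0.399).

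The other 12 lists were not called with CHIR against day 25. Alveolar type 1 genes (3 of 15 higher, 8 lower), neuroendocrine genes (3 of 15 higher, 8 lower) and hepatic genes (3 of 13 higher, 7 lower, or 8 lower adjusted over the list alone) had camera adjusted p of 0.0732, 0.0732 and 0.0819. Leaving out day 25 replicate 3 called the first (adjusted p = 0.0488), day 25 replicate 1 or 2 the second (0.0388 and 0.0201) and day 25 replicate 2 the third (0.0278). Notch (1 of 13 higher, 6 lower), endothelial and blood cell (4 of 5 higher, 1 lower), neuronal (4 of 8 lower) and intestinal genes (2 of 8 higher, 5 lower) had adjusted p of 0.0796, 0.0888, 0.136 and 0.195. Basal (4 of 15 higher, 7 lower), WNT target (7 of 15 higher, 5 lower), gastric (1 of 3 higher, 1 lower, or 2 lower adjusted over the list alone), squamous (1 of 6 higher, 1 lower) and lung field genes (8 of 20 higher, 9 lower) had adjusted p of 0.316, 0.531, 0.574, 0.652 and 0.838. Named after their values were seen, AQP5, HOPX and LMO7 were the alveolar type 1 genes that rose, FGA, FGG and SERPINA1 the hepatic genes that rose, and CALCA, SCG2 and PCSK1 the neuroendocrine genes that rose. DNAH5 rose against the other ciliated genes called, TCF21 against the mesenchymal genes and HES1 against the Notch genes, and SIK1 fell against the cAMP-responsive genes. SCGB3A2, MUC5AC and MUC16 were the secretory genes that fell, and LIN28A, DPPA4, L1TD1 and ZFP42 the pluripotency genes that fell.

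From day 25 to day 50 without CHIR, SFTPB reached 11356 ± 3624 CPM, a log2 fold change of 13.14 (SE 0.54, edgeR adjusted p = 2.07e-07), and SCGB3A2 rose by 6.33. ALB rose by 10.99, GC by 12.95 and KRT5, a basal cell keratin, by 6.57. IGFBP1, which had 0 counts at day 25, was at least 1640-fold higher. CRH, which encodes corticotropin-releasing hormone, went from 437 ± 217 to 0.15 ± 0.08 CPM. TP63 and FOXJ1 were not called against day 25 (edgeR adjusted p = 0.151 and 0.769). A total of 7166 genes were called, 3707 higher and 3459 lower, and 59.2% did not overlap (10% by chance).

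Without CHIR, 13 of 21 lists were called against day 25, and 2 held with an estimated correlation: glucocorticoid-responsive genes, higher in 11 of 11, and cAMP-responsive genes, higher in 10 of 10 (camera adjusted p = 3.07e-07 and 1.87e-05; adjusted p = 0.0392 for both with an estimated correlation). Ciliated genes rose in 16 of 22, club and goblet genes in 15 of 20 with 2 lower (16 and 2 adjusted over the list alone), basal genes in 9 of 15 with 1 lower and hepatic genes in 9 of 13 (adjusted p = 1.34e-06, 1.11e-05, 0.00185 and 1.87e-05; adjusted p = 0.278, 0.0985, 0.0784 and 0.24 with an estimated correlation). Alveolar type 2 genes rose in 11 of 17 with 2 lower (11 and 3 adjusted over the list alone) and squamous genes in 5 of 6 with 1 lower (adjusted p = 0.00133 and 0.0234; adjusted p = 0.28 and 0.303 with an estimated correlation). Cell cycle genes fell in 22 of 24, WNT target genes in 12 of 15 with 3 higher, and lung field genes in 12 of 20 with 5 higher, or 14 and 5 adjusted over the list alone (camera adjusted p = 4.72e-09, 0.00417 and 0.0119; adjusted p = 0.114, 0.288 and 0.349 with an estimated correlation). MYC, one of the 3 WNT targets that rose, rose by 4.16. Neuronal genes fell in 5 of 8 and pluripotency genes in 4 of 5 with 1 higher (adjusted p = 0.0119 and 0.0245; adjusted p = 0.114 and 0.178 with an estimated correlation). SOX9 was called higher than at day 25 without CHIR, by 1.28 (edgeR adjusted p = 0.0249), and with CHIR, by 1.21 (adjusted p = 0.0301). The first call was lost without day 25 replicate 1 or 3 or without-CHIR replicate 1 (adjusted p = 0.0644, 0.0528 and 0.0502), and the second without day 25 replicate 1 or 3 or with-CHIR replicate 1 or 2 (adjusted p = 0.0804, 0.0724, 0.0935 and 0.0733).

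The other 8 lists were not called without CHIR against day 25. Hypoxia and glycolysis genes (6 of 13 higher) had a camera adjusted p of 0.0515 and were called without day 25 replicate 3 (0.0108) or without-CHIR replicate 1 (0.0215). Endothelial and blood cell (3 of 5 higher, 1 lower, or 4 and 1 adjusted over the list alone), alveolar type 1 (5 of 15 higher, 5 lower, or 8 and 5 adjusted over the list alone), intestinal (4 of 8 higher, 2 lower) and gastric genes (2 of 3 higher, 1 lower) had adjusted p of 0.247, 0.552, 0.668 and 0.714. Notch (6 of 13 higher, 4 lower), mesenchymal (3 of 14 higher, 2 lower) and neuroendocrine genes (5 of 15 higher, 5 lower) had adjusted p of 0.787, 0.804 and 0.914. The Notch list had a median of -0.05 and a mean of 0.1, and the neuroendocrine list a median of -0.06 and a mean of 0.37, so their signs differed. Named after their values were seen, CHGA, CALCA, SCG2, PCSK1 and SCGN were the neuroendocrine genes that rose. CAV1, CAV2, HOPX, EMP2 and LMO7 of alveolar type 1 cells rose, and AGER, RTKN2, CLDN18, SPOCK2 and COL4A3 fell. COL3A1, DCN and PDGFRA of the mesenchyme rose, and TCF21 and VIM fell. DKK1 and CCND1 rose beside MYC, FOXA1, SOX9, ETV4, ETV5 and TESC were the lung field genes that rose, and POU5F1 was the pluripotency gene that rose.

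Both maturation conditions were compared with the same day 25 libraries, which alone makes their fold changes alike. A total of 1845 genes were called higher in both and 1837 lower in both, against 893 and 881.6 for independent lists. Fold changes had the same sign for 67.21% of genes, against a mean of 66.9% and at most 67.6% in 20 simulations of unchanged groups set against those libraries. The simulations called 0 genes higher in both and 0 lower in both, so their signs came from noise only. They cannot tell what share of signs shared controls give when many genes change, and no conclusion is drawn from that share. A further 648 genes were called in opposite directions, 477 lower with CHIR and higher without, and 171 the reverse, and all 648 were also called between the day 50 groups by edgeR. The covariance of the log2 fold changes across genes was 1.22 against 0.08 in the simulations, a difference of 1.14, and their correlation was 0.394 against 0.518; genes are not independent replicates. The 3 day 25 libraries are too few to be split into separate controls of at least 2 for each comparison.

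In the single-cell data, 2829 barcodes were given with CHIR and 2968 without, where 5000 cells per library had been targeted. The filters left 2251 and 2912 cells. Median depth was 2525 UMIs and 670 genes per barcode with CHIR and 3352.5 UMIs and 1035.5 genes without. Ribosomal protein genes took a median of 45.4% and 35% of UMIs. With every barcode thinned to 1000 UMIs, before the filters and with 0 left out, medians were 362 and 441 genes. Under 500 genes were detected in 569 barcodes with CHIR and 44 without.

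Cells of the conditions hardly mixed: each of the 9 clusters was almost wholly of 1 library, and 5151 of 5163 cells belonged to the main library of their cluster, so clusters and libraries can hardly be separated. A basal-like cluster, led by S100A2, COL3A1 and COL17A1 and also raised for the mesenchymal markers COL1A1, COL1A2, COL3A1 and TAGLN, held 11.44% of cells without CHIR (95% Clopper-Pearson interval 10.3 to 12.65) and 0.04% with it. The share without CHIR was 7.18% at resolution 0.4. The cluster's level of the epithelial gene EPCAM, 101.4 CPM, was the lowest of the 9 clusters. A hepatic-like cluster led by SPP1 with SERPINA1 and ALB held 20.05% without CHIR (18.61 to 21.56) and 0 of 2251 cells with it, a count of cluster members that sets no limit on such cells in unnamed clusters. It held 12.6% without CHIR when at least 1000 genes per cell were required. SCGN, 1 of the 6 neuroendocrine genes called higher in bulk, was also raised in this cluster, and no cluster was named neuroendocrine-like. A further 9.03% of cells without CHIR lay in an unnamed cluster with 4 raised hepatic markers, none among its leading genes, which included HNF4A of the hepatic gene list and SPP1, ITIH2, TM4SF4 and DKK1, shared with the hepatic-like cluster. An AT2-like cluster, led by PGC and SFTPA1 and also raised for 5 proliferation markers, held 3.64% of cells with CHIR (2.91 to 4.5) and 0.07% without; it had the second highest median depth, 4339.5 UMIs, and no cluster got this name under 4 of 6 other settings. With at least 1000 genes per cell, 1 of these 4, a cluster led by PGC and SFTPA1 with 6 raised AT2 markers held 57 cells with CHIR and 1 without, but was named proliferating for its 8 raised proliferation markers. Doublets were not effectively removed, and 96.31% of cells with CHIR and 68.44% without stayed unnamed.

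**Figure D2:**
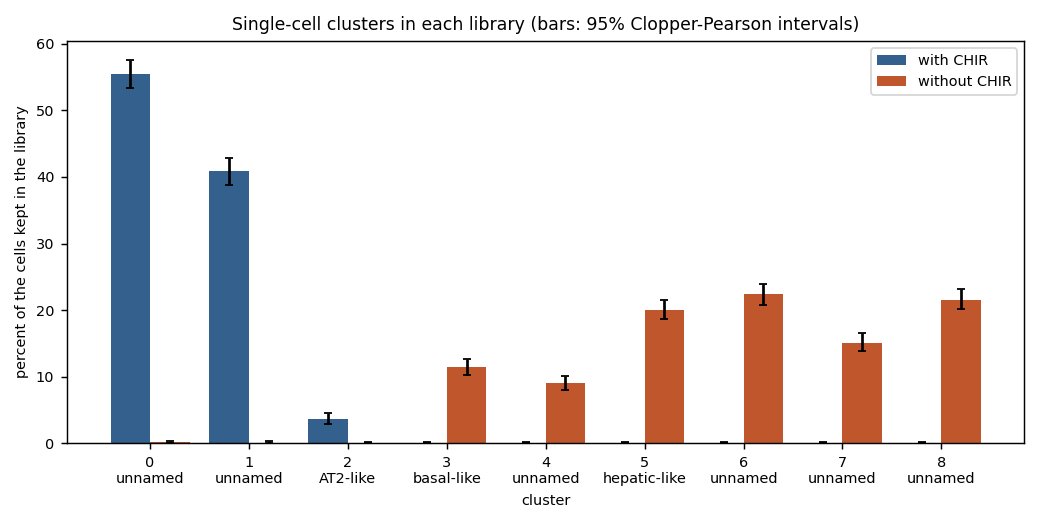
Percent of the kept cells of each single-cell library in each of 9 clusters, with 95% Clopper-Pearson intervals. Each cluster held cells almost wholly of 1 library, such as 20.05% of cells without CHIR and 0 with CHIR in the hepatic-like cluster.

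Summed over cells, the genes with the highest ratios without CHIR were CCL2, SPP1, INHBA, CDH6, SCGB3A2 and ALB. SCGB3A2 was 579-fold higher (95% Poisson interval 339 to 1090), a ratio that fell to 189 with all barcodes, and SPP1 was at least 803-fold higher. The lowest ratios were those of NDUFA4L2, NRN1, FAM159B, IGF1, RP11-90D4.3 and STC1, with NDUFA4L2 at 280 CPM with CHIR and 0.334 without. NKX2-1 had a ratio of 0.235 (0.202 to 0.272), LGR5 0.0482 (0.0172 to 0.11) and SFTPB 3.84 (3.67 to 4.02). SOX9 had a ratio of 2.43 (2.1 to 2.83), where bulk gave no call. FOXJ1 had only 11 and 12 UMIs, a ratio of 0.684 (0.276 to 1.71), and the interval excludes the 9.87-fold higher level found in bulk. These values have no replicate check.

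The median log2 ratio of all genes was 0.44, and random lists had medians of 0.3 to 0.47. Lists far above these were hepatic (3.85), alveolar type 1 (2.7) and basal genes (2.41), each at percentile 100. So were squamous (at least 4.15) and mesenchymal genes (at least 3.23), whose medians are lower bounds, since the middle member had 0 UMIs with CHIR and was set to the floor of 3. Glucocorticoid, cAMP, Notch and club and goblet genes had medians of 1.43, 1.38, 1.29 and 1.23, at percentiles 99.8, 99.2, 98.9 and 99.6. Hypoxia and glycolysis (-2.55), WNT target (-2.02) and alveolar type 2 genes (-1) were at percentile 0, endothelial and blood cell genes (-1.02) at 0.4, cell cycle genes (-0.39) at 0.1 and lung field genes (-0.05) at 1.5. Neuronal (1.51), neuroendocrine (0.69), intestinal (0.11) and ciliated genes (-0.02) were at percentiles 95, 81, 35.2 and 13. Of genes called in bulk with at least 50 UMIs, 72.68% (3020 of 4155) had the same sign in the single-cell sums, against 53.73% of genes not called. The share was 93.56% for genes called higher and 54.9% for genes called lower. Relative to the median ratio of all genes compared, a scaling added after the data were seen, it was 83.78% and 80.12%. Genes not called had 60.8% on that scaling.

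**Figure D3:**
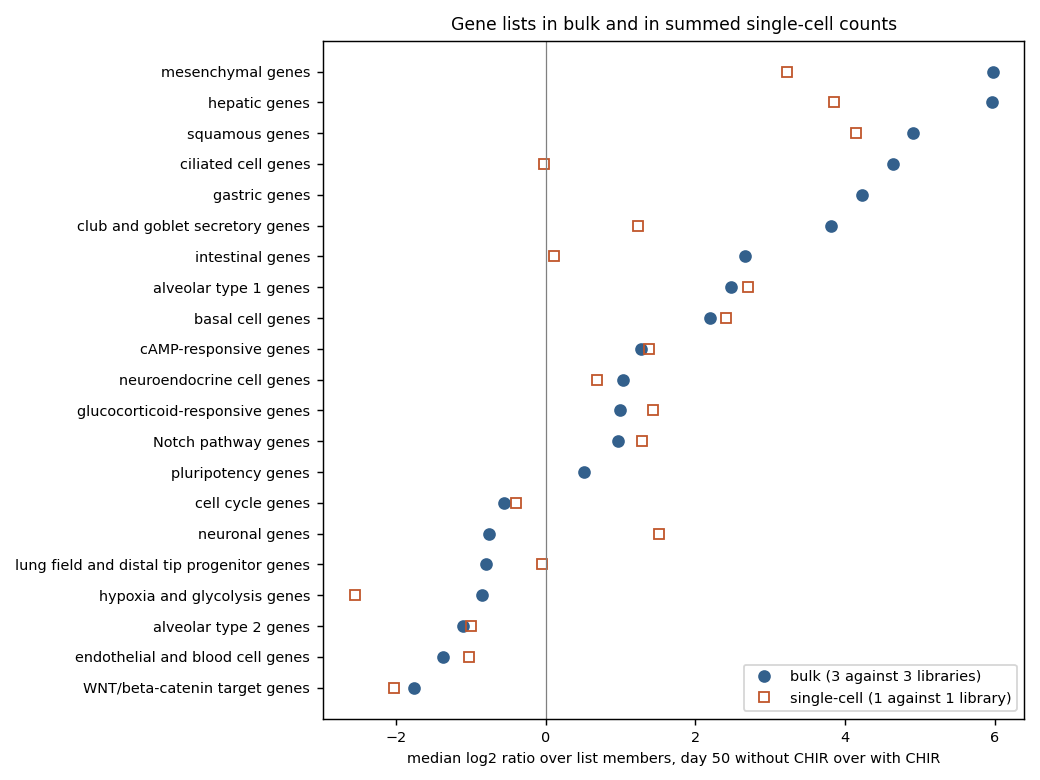
Median log2 ratio of day 50 without CHIR over with CHIR for each gene list, in bulk (filled circles, 3 against 3 libraries) and in summed single-cell counts (open squares, 1 against 1 library). Hepatic genes were high in both, at 5.96 and 3.85, and ciliated genes were at 4.64 in bulk and -0.02 in single cells; the single-cell squares of squamous and mesenchymal genes are lower bounds.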

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

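Several tests were chosen after the results were seen. These were the tests of hepatic levels in SCGB3A2 and SFTPB cells and of epithelial levels in collagen cells. The tests of genes per barcode at 1000 UMIs and of other splits were also chosen then. A total of 19 named genes were called in opposite directions since day 25 with and without CHIR, and the difference between those changes is the edgeR test of day 50 without against with CHIR. In log2 units it was 12.75 for KRT4, 10.95 for SCGB3A2, 10.19 for KRT5, 8.78 for DKK1, 7.89 for COL3A1, 7.71 for PDGFRA, 6.46 for COL17A1, 5.92 for SCGN, 3.34 for NRARP, 3.11 for JAG1, 2.72 for ISX and 2.4 for SIK1. It was -9.02 for NOTUM, -8.39 for SOX14, -7.7 for POU3F2, -3.64 for LGR5, -2.44 for RNF43, -1.95 for FOXP2 and -1.55 for NKX2-1. The fitted values of KRT4, SOX14 and POU3F2 depend on the default prior count of edgeR, since the lower group had 0 to 3 counts. The call of NKX2-1 with CHIR against day 25 was lost when day 25 replicate 3 or with-CHIR replicate 2 was left out.

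For the counts of genes called, the 6 libraries of each comparison make 10 splits, too few for a share under 0.05. Day 50 without against with CHIR called 7237 genes and the highest other split 824. With CHIR against day 25 called 7485 and without CHIR against day 25 called 7166, and the highest other split called 0 in both. In each comparison 1 of 10 splits, the real one, reached its count.

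Hepatic genes were higher without CHIR in all 13 cases in bulk. In 322 cells with at least 20 UMIs of SCGB3A2 and SFTPB (median 4144.5 UMIs), hepatic genes without SERPINA1 reached 322.6 CPM. This was 62.3% of the level in clusters with raised hepatic markers, against 27 CPM in basal-like cells (median 3044 UMIs) and 146.8 CPM in the library with CHIR. A hepatic UMI was found in 8.1% of basal-like cells and in only 42.5% of the 322 cells. Of the 322 cells, 318 lay outside the clusters with raised hepatic markers. ALB and AFP alone gave a mean of 188.3 CPM in these 318, from 295 UMIs in 76 cells with 51 in a single cell. The level was 4.9 CPM in basal-like cells and 0.4 CPM with CHIR. Doublets with hepatic-like cells, or their free RNA, were tested as the whole source. Per UMI of ALB and AFP, 8 other leading genes of the hepatic-like cluster reached 24.2% of their lowest ratio in the hepatic clusters (95% bootstrap interval 16.4 to 38.7). Such a source would keep the ratio, and the bound set in advance against it was 50%. The 8 genes were, however, chosen in the same data for a higher level in that cluster than in all other cells, the tested cells among them. This choice favours a low ratio and the interval does not cover it, so no conclusion is drawn. Separate hepatic-like cells, doublets, also with cells richer in ALB and AFP, and free RNA stay open. The absence of CHIR itself stays open too, untested.

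Mesenchymal genes were higher without CHIR in both assays, which were taken apart after the results were seen. In the single-cell library COL1A1 had 1072 UMIs, CDH11 645, COL3A1 551, COL6A1 276, FBLN1 134, LUM 6, PDGFRA 2 and DCN 1. Outside the basal-like cluster, 99 cells had at least 3 collagen UMIs. They had 144.2% of the EPCAM and keratin level of cells with fewer, and 120.6% of the EPCAM level. The basal-like cluster, low in EPCAM, was set apart after values per cluster had been seen, and its cells with fewer collagen UMIs stayed in the reference. Both choices favour high values. These pooled levels argue against the 99 cells being mesenchymal as a whole, but cannot exclude a minority of mesenchymal cells. For the 78 cells with at least 3 collagen UMIs in the basal-like cluster the values were 43.7% and 30%, between the bounds of 25% and 50%. Their EPCAM and keratin level of 1039.6 CPM was close to the 1067.8 CPM of the whole cluster. Mesenchymal cells therefore cannot be told apart there from basal-like cells with collagen transcripts. In bulk, where DCN and LUM rose with COL3A1, a second list of 13 mesenchymal genes, fixed before their values were seen, had 9 higher and 0 lower. That share of 69.2% fell between the 75% set in advance for mesenchymal cells and the 25% set against them. A change within epithelial cells could raise such a list too, so a share over 75% would not have shown mesenchymal cells either. Their presence cannot be told apart from such a change.

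Fewer genes were detected per barcode with CHIR. Over all barcodes, shallower sequencing as the whole cause is argued against. At 1000 UMIs those with CHIR still had 82.1% of the genes per barcode of those without. They included 569 barcodes with CHIR and 44 without that had under 500 genes and were later filtered out. At 500 UMIs outside ribosomal protein and mitochondrial genes, in the kept cells only, the value was 91.9%. It lay between the bounds of 90% and 95%, so a larger ribosomal share cannot be told apart from a narrower set of genes. The 82.1% and 91.9% cover different barcodes and are not to be set against each other. CHIR itself, with 1 library per condition, was not tested.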

How the results depend on the processing

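The settings with scaled genes, with signs relative to the median ratio and with signs without mitochondrial and ribosomal protein genes were chosen after seeing the data. Of 134 named-gene results, 1638 values under the alternatives kept direction and side of the threshold, 20 in 5 results lost the call and 3 in 2 results gained it; none reversed. With each library left out, genes called ranged from 5922 to 7484 without against with CHIR, 6069 to 7860 with CHIR against day 25 and 5655 to 7161 without CHIR against day 25, genes changed alike from 2799 to 4042, and lists called from 11 to 13, 8 to 10 and 13 to 14. Replicate numbers were not taken as pairs: 4 of 9 same-number pairs had correlated deviations over 0.1 (range -0.06 to 0.6), and 3 of 9 libraries correlated best with their own number. Partial pairing stays open, since those 3 were the replicate 1 libraries and the value of 0.6 joined replicates 3 with and without CHIR. With the number as a block, 8064, 8231 and 7992 genes were called, MUC5AC (adjusted p = 0.0269; 0.029 with the DESeq2 Wald test), Notch genes (0.0484, without against with CHIR) and hypoxia genes (0.0175, without CHIR against day 25) were gained and no named gene or list lost its call. With an estimated correlation camera called 0, 0 and 2 lists instead of 12, 9 and 13. A correlation above the preset 0.01 is argued against as the cause for alveolar type 1 and basal genes without against with CHIR. Their estimates were 0.01 and 0, yet the camera adjusted p rose from 0.00277 to 0.165 and from 0.000164 to 0.0853. The cAMP-responsive list, not called there, had an estimate of -0.03, and its camera adjusted p rose from 0.163 to 0.372. Estimates of the other lists called in that comparison ranged from 0.06 to 0.62, and the cause was not tested. The higher adjusted p-values with an estimated correlation are therefore not to be read as an effect of correlation between genes alone. At an adjusted p of 0.01, 2265 genes instead of 3682 changed alike, since the threshold is stricter. For bulk lists, 517 values were alike, 38 in 32 results lost the call and 12 in 6 results gained it. No cluster was named AT2-like, a share of 0 in both libraries with 1000 genes per cell, a 10% mitochondrial limit, resolution 0.4 or scaled genes, and the share was 5.86% with CHIR with doublets kept. Basal-like cells without CHIR fell to 9.2% with 1000 genes and 7.18% at resolution 0.4. Hepatic-like cells were 12.6% with 1000 genes, 18.02% at the 10% limit, 18.09% with doublets kept and 15.62% with scaled genes. With 1000 genes the cluster led by PGC and SFTPA1 stayed but was named proliferating; for the other shifts the cause was not tested. Same-sign shares were 81.81% relative to the median ratio and 78.61% without mitochondrial and ribosomal protein genes, against 60.8% and 58.34% of genes not called. Leaving out mitochondrial and ribosomal protein genes moved the median of all single-cell ratios from 0.44 to 0.17 and the intestinal list from 0.11 to -0.18. Depth limits genes of few UMIs, such as AGER with 4 and 6, whose ratio of 0.94 had an interval of 0.223 to 4.53.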

Other observations

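These observations were chosen after their values were seen. Ciliated cell genes differed between the assays. All 22 were called higher without CHIR in bulk, while the 9 with at least 20 UMIs had a single-cell median log2 ratio of -0.02, with 4 higher and 5 lower, and no cluster met the rule for a ciliated-like name, which does not exclude such cells within other clusters. The labels do not say whether both assays used the same cultures, and no explanation was tested.

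Cell cycle genes were called in both directions without CHIR. The mitotic gene UBE2C fell by 1.62 on the log2 scale while RRM2, which makes deoxynucleotides for DNA synthesis, rose by 1.5 (edgeR adjusted p = 0.00041 and 0.00103). The other 3 that rose, named after their values were seen, were the replication helicase genes MCM4, MCM5 and MCM6, by 0.8, 1.1 and 0.88, while MCM2, MCM3 and MCM7 were not called (adjusted p = 0.287, 0.133 and 0.806).

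With CHIR, 55.49% of cells lay in a cluster led by TFF3, NDUFA4L2, BNIP3 and NDRG1, and 40.83% in one led by STC1 and SOX11. Without CHIR, 22.36% lay in a cluster led by MMP7 and SAA1, 21.6% in one led by ANKRD1 and IFI6, and 15.14% in one led by SCGB3A2, SFTPB and SCGB1A1, which had 4 raised alveolar type 1 and 3 raised secretory markers. The last of these stayed unnamed, since its leading genes held more secretory markers (SCGB3A2, SCGB1A1, SCGB3A1) than alveolar type 1 markers (EMP2, HOPX).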
